A study of Mus musculus with 72 samples.

How the data were processed

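RNA was sequenced from Eμ-Myc B-lymphoma cells in 72 libraries: 48 from 24 mice of the acute study (6 per treatment) and 24 from 12 early-passage lines of the relapse study (3 per treatment), with 1 input and 1 polysomal library for each mouse or line. Per the labels, RNA was depleted of ribosomal RNA and read as single-end reads of 50 bp, and the authors aligned reads with TopHat2 to GRCm38 and counted them with HTSeq; versions, annotation and strand are not stated. The 4 deposited tables hold raw counts per gene symbol, with 35149 and 30901 genes in the acute input and polysomal tables and 35556 in each relapse table. Every sample column of the 4 tables was used. Each relapse table holds 27 gene names that were turned into dates, which were tested like any other gene but are not named. Counts of reads with no gene or with several were left out of the totals.

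Each fraction of each study was fitted with the edgeR 4.0.16 quasi-likelihood test, with TMM normalization, filterByExpr and all 4 treatments in 1 model, and p values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Levels are log2 counts per M (CPM) with a prior count of 2. Translational efficiency was the fraction by treatment term of a model with a block on each mouse or line. The replicate numbers do not pair mice across treatments: the mean correlation of libraries with the same number was 0.012 in the input and -0.026 in the polysomal RNA, so number was used as a block in an alternative alone. The input and polysomal library of a mouse matched best with each other in 21 of 24 mice. Standard errors are the log2 fold change over the square root of its F statistic, and mean levels of marker lists were compared by exact permutation of the group labels, adjusted over 42 tests.

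Gene lists were 31 sets of pathways, complexes and cell type markers, written before the data were examined, of which 31 were tested in the acute and 29 in the relapse study (at least 5 measured members). Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Histone, ribosomal protein and immunoglobulin genes have related sequences elsewhere in the genome, so their counts can hold reads of other loci. For genes near 0 in a group, the fold is the ratio of summed counts scaled by library size, with its 95% counting interval, which does not cover differences between lines; where a group had no counts it was set to a floor of 3 counts over the group.

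Genes are named by a rule written before the data were examined: among genes past the threshold, with a mean of at least 2 log2 CPM and with all treated libraries on the same side of the control mean, the 3 largest rises and falls in the input, the 5 largest in the polysomal RNA and in translational efficiency, the 3 largest for comparisons of the combination with a single agent, and up to 2 members per direction of each called list. Names made of a clone number were passed over, and 12 genes were named whatever their result. Genes outside the rule are marked in the text.

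Library totals had a median of 19 M in the acute input, 17.4 M in the acute polysomal RNA, 20.5 M in the relapse input and 21.2 M in the relapse polysomal RNA. The test was run on simulated counts with the spread of each gene. Genes were drawn independently, without batches or other structure of the samples, and changes were planted in well-counted genes outside the lists. The shares below hold for such data and can differ in the real libraries. For combination against control, 1.5-fold, 2-fold and 4-fold changes were called in 85.1%, 98.5% and 100% of planted genes in the acute input, 76.1%, 95.5% and 100% in the acute polysomal RNA, 74.6%, 94% and 100% in acute translational efficiency, 10.4%, 53.7% and 93.9% in the relapse input, 2.99%, 32.8% and 78.8% in the relapse polysomal RNA and 0%, 11.9% and 71.2% in relapse translational efficiency. Of the genes called by edgeR, 3.5% to 6.6% had no planted change. With DESeq2 these were 12% and 11% in the acute input and polysomal RNA, 13% in the relapse input and 25% in the relapse polysomal RNA, so it made more false calls in simulated data. DESeq2 was not simulated for translational efficiency.

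Alternatives written before the data were examined were DESeq2 1.42.0, RLE size factors, no count filter, the compared groups alone, a block on replicate number, no block in translational efficiency, each relapse line left out in turn, and the 2 other list tests. Alternatives added after seeing the data left out 3 acute input libraries with over 10% of counts on Gm26870 and Gm10800, 4 acute polysomal libraries with over 10% on Lars2 and Yam1, both libraries of vehicle mouse 6 and combination mouse 3, everolimus mouse 3, or the polysomal libraries of CX5461 lines 14 and 39, or added the run of columns in the relapse tables as a term. Shares of counts in single libraries carry Wilson intervals, which cover counting error alone. Gene positions are from the GENCODE vM21 annotation of GRCm38. Work was done in R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.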

Results

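RNA was counted in B-lymphoma cells of the Eμ-Myc mouse, in which a Myc transgene drives the disease, in an acute and a relapse setting. For the acute setting, mice carrying clone 4242 cells received vehicle, CX5461 at 35 mg/kg, everolimus at 5 mg/kg or both drugs on day 10 after transplantation, and lymph nodes were taken 2 h later, with 6 mice per group. CX5461 inhibits RNA polymerase I, which transcribes the ribosomal RNA genes, and everolimus inhibits mTORC1, a kinase complex that promotes translation. For the relapse setting, lines of clone 107 kept for 2 to 3 passages came from mice whose lymphoma had regrown under each treatment, with 3 lines per group, and those from vehicle mice are called naive. Each mouse or line gave 1 library of cytoplasmic input RNA and 1 of polysomal RNA, from mRNA with at least 4 ribosomes, which made 72 libraries. Total counts per library were 17.1 to 24.7 M in the acute input (median 19 M), 11.5 to 20.9 M in the acute polysomal RNA (17.4 M), 14.6 to 26 M in the relapse input (20.5 M) and 15.5 to 30.4 M in the relapse polysomal RNA (21.2 M). Changes are log2 fold changes ± SE from edgeR, with n = 6 mice or n = 3 lines per group, and p values are adjusted over the genes tested. The 3 drug groups of a setting share 1 control group, so genes called in several comparisons are not independent findings.

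The first acute comparison asks which cytoplasmic transcripts CX5461 alone changed within 2 h. Interferon-stimulated transcripts fell: Oas3, an interferon-induced oligoadenylate synthetase (chromosome 5, 120753098 to 120777661), changed by -0.93 ± 0.18 (adjusted p = 0.0209), Usp18, the protease that removes ISG15 (chromosome 6, 121245906 to 121270917), by -0.95 ± 0.21 (0.046), and interferon-induced Rtp4 by -0.92 ± 0.20 (0.0347). Of the 26 measured members of the type I interferon list, 10 fell, among them the transcription factor Irf7 (-0.78 ± 0.14), and 24 were lower when adjusted over the list alone. T cell markers fell with them: Lat and Zap70, an adaptor and a kinase of T cell receptor signalling, changed by -0.98 ± 0.17 and -0.58 ± 0.11, and 4 of 24 T cell markers were lower (18 adjusted over the list alone). The mean level of that list was 0.54 lower than after vehicle (difference -0.54, adjusted p = 0.0151, exact permutation test, n = 6), and NK cell markers differed by -0.48 (adjusted p = 0.0341), with perforin, Prf1, at -0.88 ± 0.15. Rrp15, a ribosome biogenesis factor, rose by 0.28 ± 0.06, and the other gene called higher, Gm6169 (0.31 ± 0.07), was named after its value was seen. The polymerase I subunit Polr1b (-0.09 ± 0.09) and the polymerase I initiation factor Rrn3 (-0.12 ± 0.06) did not pass.

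Across the 16055 genes tested in the acute input, CX5461 changed 64 genes, 2 higher and 62 lower. The list calls for interferon, T cell and NK cell genes held with an estimated correlation (adjusted p = 0.0276, 0.0276 and 0.0403). The 79 cytosolic ribosomal protein genes had a median of 0.12 with 0 called by edgeR, and their call ended (adjusted p = 0.561 with an estimated correlation), as did that of cholesterol biosynthesis, with a median of -0.14 (adjusted p = 0.406 with an estimated correlation). Reads on Gm26870 and Gm10800 made up 23.3% of the counts of CX5461 mouse 4, 18.4% of everolimus mouse 2 and 15% of CX5461 mouse 6. Without these 3 input libraries 1 gene was called, and none of the genes named here passed. The medians were then -0.69 for interferon, -0.56 for T cell and -0.49 for NK cell genes, against -0.62, -0.60 and -0.42, and all 3 list calls ended (adjusted p = 0.0597 with an estimated correlation). Without vehicle mouse 6 and combination mouse 3 the first 2 list calls held and that of NK cells ended (adjusted p = 0.0609 with an estimated correlation). The gene count was 35 with the vehicle and CX5461 libraries alone and 154 with DESeq2.

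Everolimus alone lowered transcripts of the integrated stress response in the input. Trib3, a pseudokinase induced by ATF4 (chromosome 2, 152337422 to 152344032), fell 3.11-fold (-1.64 ± 0.21, adjusted p = 0.00052), Atf4 itself (chromosome 15, 80255184 to 80257541) changed by -0.62 ± 0.09 (0.00263) and Sesn2, a stress-induced inhibitor of mTORC1, by -0.67 ± 0.14 (0.0474). These were the 3 of 41 measured ATF4 targets that passed, and 19 were lower when adjusted over the list alone. This list call held (adjusted p = 0.00753 with an estimated correlation, and 0.04 without the 3 libraries rich in Gm26870 and Gm10800). Among 24 glycolysis genes, Hk2, which phosphorylates glucose (chromosome 6, 82725025 to 82774454), changed by -0.48 ± 0.07 and the enolase Eno3 by -0.78 ± 0.14, with 9 lower when adjusted over the list alone and adjusted p = 0.0581 with an estimated correlation. Transcription regulators were the largest rises by the naming rule: Crebrf (0.58 ± 0.12), Hbp1 (0.55 ± 0.09) and the clock receptor Nr1d2 (0.51 ± 0.08). Myc (-0.06 ± 0.09) and Eif4ebp1, the mTORC1-controlled repressor of translation (-0.31 ± 0.10), did not pass.

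In all, everolimus changed 17 input genes, 7 higher and 10 lower, and 6 without the 3 libraries rich in Gm26870 and Gm10800, 75 without vehicle mouse 6 and combination mouse 3 and 123 with DESeq2. Everolimus mice 1 and 3 had the most alike input libraries of any pair, with a median variance 1.32 times that of sampling, against 2.11 for the next pair. The mean over genes was 2.93 times that of sampling. Their polysomal libraries were not among the 3 most alike pairs of that fraction, whose medians were 3.26 to 4.03. Whether everolimus 1 and 3 are 2 distinct mice cannot be read from the counts, and n = 6 for everolimus assumes it. Without mouse 3 the count was 8, with Crebrf, Eno3 and Sesn2 past the threshold no longer (adjusted p up to 0.146). The interferon list had a median of -0.30 with 0 genes called by edgeR (adjusted p = 0.33 with an estimated correlation), while T cell markers differed by -0.14 in mean level (adjusted p = 0.636, exact permutation test). TCA cycle genes, with a median of -0.15, and ribosome biogenesis factors, with a median of -0.09, lost their list calls (adjusted p = 0.348 with an estimated correlation for both).

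After both drugs, interferon-stimulated and stress-response transcripts were lower in the input. Of the 26 interferon genes, 25 fell, among them Ifit1 (-1.34 ± 0.22, adjusted p = 0.00138), Usp18 (-1.32 ± 0.22), the ubiquitin-like modifier Isg15 (-1.29 ± 0.20), Ifit3 (-1.22 ± 0.18) and Oas3 (-1.15 ± 0.18). The list had a median of -0.82 and adjusted p = 0.0679 with an estimated correlation. Of the 41 ATF4 targets, 22 fell (25 adjusted over the list alone), with Trib3 3.49-fold lower (-1.80 ± 0.21) and the tyrosyl-tRNA synthetase Yars at -0.62 ± 0.10, and this list call held (adjusted p = 0.0305 with an estimated correlation). It ended without the 3 libraries rich in Gm26870 and Gm10800 (0.0725) and without vehicle mouse 6 and combination mouse 3 (0.135). Those 3 libraries are of CX5461 and everolimus mice, so they enter this comparison only through the fit shared by all groups. Without them the list median stayed at -0.325 and 22 targets still fell. In glycolysis, 7 of 24 genes fell, with Hk2 at -0.48 ± 0.07 and the phosphofructokinase Pfkp at -0.50 ± 0.10 (1 higher and 15 lower adjusted over the list alone, adjusted p = 0.11 with an estimated correlation).

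T cell markers fell in 14 of 24 cases, including Zap70 (-0.86 ± 0.11) and the receptor chain Trbc2 (-0.96 ± 0.16), and 3 of 9 NK cell markers fell, including Eomes (-1.05 ± 0.28). Their list calls ended with an estimated correlation (adjusted p = 0.11 and 0.103), and the mean levels of these lists differed from vehicle by -0.6 and -0.65 (adjusted p = 0.026 and 0.0151, exact permutation test, n = 6). Of 66 histone genes, Hist1h1a (-0.60 ± 0.18) and Hist2h4 (-0.69 ± 0.21) fell and H1f0, a linker histone made outside S phase, rose by 0.34 ± 0.10. Adjusted over the list alone, 61 were lower and 2 higher (adjusted p = 0.585 with an estimated correlation). The replication gene Fen1 (-0.46 ± 0.12) was 1 of 5 lower among 36 (10 adjusted over the list alone, adjusted p = 0.585 with an estimated correlation). Citrate synthase, Cs (-0.24 ± 0.07), was 1 of 3 lower among 26 TCA genes (14 adjusted over the list alone, adjusted p = 0.585 with an estimated correlation). Mrpl40 (-0.34 ± 0.08) was 1 of 10 lower among 76 mitochondrial ribosomal proteins and Fdps, of sterol synthesis (-0.72 ± 0.15), 1 of 3 among 24 (17 and 5 adjusted over the list alone, adjusted p = 0.616 for both with an estimated correlation).

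The largest rises by the naming rule were the calcium channel Cacna1h (1.05 ± 0.31), Cpeb2, a regulator of mRNA polyadenylation (0.94 ± 0.20), and the glycosyltransferase Galnt15 (0.91 ± 0.28). The pro-apoptotic gene Bmf (0.82 ± 0.22) and the kinase Pim1 (0.35 ± 0.10) rose, Eif4ebp1 (-0.52 ± 0.10) and Rrn3 (-0.22 ± 0.06) fell, and Myc (-0.03 ± 0.09) did not pass. The combination changed 1201 input genes, 531 higher and 670 lower. The count was 701 with no count filter, 685 with the vehicle and combination libraries alone, 1921 with DESeq2 and 3590 without vehicle mouse 6 and combination mouse 3. Reads with no gene made up 11.5% to 19.7% in the input after the combination and 6.07% to 14.9% after vehicle. This share differs with treatment, and its bearing on the combination calls was not tested.

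**Figure D1:**
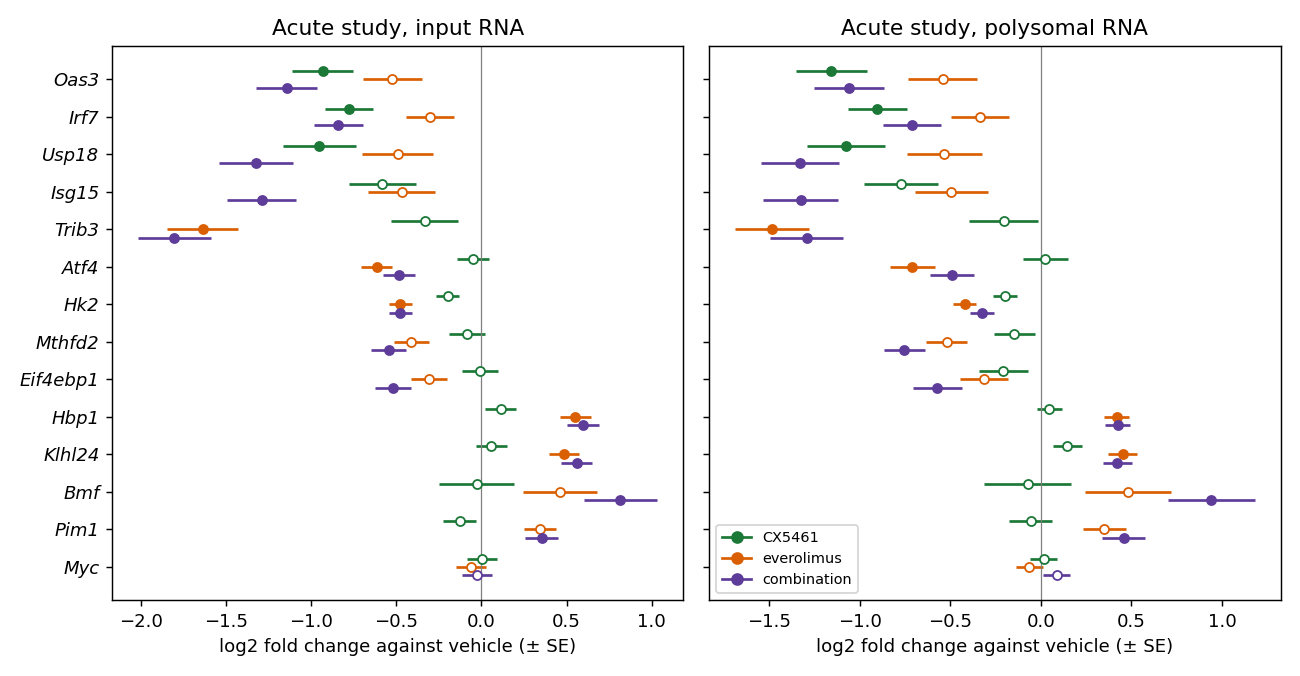
Log2 fold changes against vehicle (points, with SE bars) of 14 genes, after CX5461, everolimus and the combination, in the acute input (left) and polysomal RNA (right), 6 mice per group; filled points have an adjusted p under 0.05 in edgeR. Trib3 and Hk2 are lower after everolimus and the combination, and Oas3 and Usp18 after CX5461 and the combination.

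In polysomal RNA, the genes lower after CX5461 included interferon-stimulated transcripts and T cell markers, but no list call held with an estimated correlation. This fraction also held the non-coding RNAs Rn7sk and Rpph1, so presence in it does not by itself show that a transcript was engaged by ribosomes. Oas3 (-1.16 ± 0.20, adjusted p = 0.00885), the interferon-induced GTPase Mx1 (-1.09 ± 0.21), Oas2 (-1.08 ± 0.19), Usp18 (-1.08 ± 0.21) and the IgM receptor gene Faim3 (-0.97 ± 0.18) were the largest falls by the naming rule. Of 26 interferon genes, 10 fell (24 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation). The T cell transcription factor Bcl11b (-0.82 ± 0.13) and kinase Lck (-0.52 ± 0.10) were 2 of 3 T cell markers that fell among 24 (19 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation). Of 8 NK cell markers 0 were called by edgeR (5 lower adjusted over the list alone, adjusted p = 0.189 with an estimated correlation). Mean levels of T cell and NK cell markers differed from vehicle by -0.48 and -0.52 (adjusted p = 0.0151 for both, exact permutation test, n = 6). Rises were led by the chemokine Ccl9 (0.80 ± 0.14), the adhesion molecule Jam2 (0.73 ± 0.18), the lipid droplet coat Plin2 (0.63 ± 0.13), Klhl41 (0.62 ± 0.09) and Asnsd1 (0.57 ± 0.10). Myc (0.02 ± 0.07) and Rrn3 (-0.03 ± 0.07) did not pass, and Mvd (-0.35 ± 0.08) was the 1 cholesterol gene of 24 that fell (adjusted p = 0.713 with an estimated correlation).

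CX5461 changed 135 of 15374 polysomal genes, 26 higher and 109 lower. Lars2 and Yam1 took 26.2% of the counts of vehicle mouse 2 (95% Wilson interval 26.1 to 26.2), 19.8% of vehicle mouse 5, 10.8% of CX5461 mouse 6 and 10.1% of vehicle mouse 6. Without these 4 polysomal libraries 1 gene was called, and Klhl41 was the 1 named gene that passed. The medians were then -0.74 for interferon, -0.70 for T cell and -0.53 for NK cell genes, against -0.66, -0.55 and -0.53. The count was 83 with no count filter, 47 without vehicle mouse 6 and combination mouse 3 and 365 with DESeq2.

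After everolimus, the polysomal RNA showed lower stress-response transcripts. Trib3 fell 2.80-fold (-1.49 ± 0.20, adjusted p = 0.00081), Atf4 changed by -0.71 ± 0.12 and Atf5 by -0.54 ± 0.11, the 3 of 41 ATF4 targets that passed (13 adjusted over the list alone), and the list call held (adjusted p = 0.0392 with an estimated correlation). It ended without the 4 libraries rich in Lars2 and Yam1 (0.312) and without vehicle mouse 6 and combination mouse 3 (0.178). All 79 cytosolic ribosomal protein genes had negative estimates, with a median of -0.17, 0 called by edgeR over all genes and 5 lower when adjusted over the list alone (adjusted p = 0.236 with an estimated correlation). The 30 other mRNAs with a 5′ terminal oligopyrimidine (TOP) tract had a median of -0.11 (3 lower adjusted over the list alone, adjusted p = 0.125 with an estimated correlation). Hk2 (-0.42 ± 0.07) was the 1 of 24 glycolysis genes that fell (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.218 with an estimated correlation), and Aldoart1, an aldolase retrogene whose counts can hold reads of its parent gene (-0.71 ± 0.13), and the ubiquitin ligase Siah2 (-0.57 ± 0.10) fell too. The ubiquitin ligase subunits Fbxl20 (0.51 ± 0.07) and Klhl24 (0.45 ± 0.08), Hbp1 (0.42 ± 0.07), cyclin G2, Ccng2 (0.39 ± 0.07), and Kdsr, of sphingolipid synthesis (0.38 ± 0.05), rose. Eif4ebp1 (-0.32 ± 0.13) and Myc (-0.07 ± 0.07) did not pass.

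Everolimus changed 23 polysomal genes, 7 higher and 16 lower. The count was 7 without everolimus mouse 3, where Atf4, Siah2, Aldoart1 and Atf5 passed the threshold no longer (adjusted p up to 0.152). It was 4 without the 4 libraries rich in Lars2 and Yam1, where Fbxl20, Hbp1, Trib3 and Atf4 were the named genes that passed. With no count filter it was 12, with the vehicle and everolimus libraries alone 10, without vehicle mouse 6 and combination mouse 3 44, and with DESeq2 94.

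With both drugs, most polysomal interferon and T cell transcripts fell, and no list call held with an estimated correlation. Pydc3, an interferon-inducible pyrin domain gene (-1.51 ± 0.18, adjusted p = 5.06e-05), Usp18 (-1.33 ± 0.22), Isg15 (-1.33 ± 0.21), Rtp4 (-1.27 ± 0.23) and the interferon-induced GTPase Tgtp2 (-1.25 ± 0.21) were the largest falls by the naming rule, and 23 of 26 interferon genes fell (25 adjusted over the list alone, adjusted p = 0.0968 with an estimated correlation). T cell markers Skap1 (-1.13 ± 0.21) and Trbc2 (-1.05 ± 0.19) were among 16 of 24 that fell (21 adjusted over the list alone), and Nkg7 (-1.31 ± 0.21) and Eomes (-1.30 ± 0.33) were 2 of 3 lower among 8 NK cell markers (5 adjusted over the list alone). Both calls ended with an estimated correlation (adjusted p = 0.101 for both). The mean levels of the T cell and NK cell lists differed from vehicle by -0.68 and -0.74 (adjusted p = 0.0151 for both, exact permutation test, n = 6). The folate enzyme Mthfd2 (-0.75 ± 0.11) and Trib3 (-1.29 ± 0.20) were among 17 of 41 ATF4 targets that fell (2 higher and 23 lower adjusted over the list alone, adjusted p = 0.0968 with an estimated correlation).

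A minority of genes of energy metabolism and of the ribosome passed in the same libraries. Among nuclear-encoded OXPHOS subunits 5 of 77 fell, such as Ndufs5 (-0.28 ± 0.07), and 27 were lower adjusted over the list alone. Among mitochondrial ribosomal proteins 6 of 76 fell, such as Mrps6 (-0.41 ± 0.11), and 16 were lower adjusted over the list alone. Among cytosolic ribosomal proteins 5 of 79 fell, such as Rpl35a (-0.30 ± 0.08) and Rpl7a (-0.27 ± 0.08), and 14 were lower adjusted over the list alone. Of 13 mitochondrially encoded subunits mt-Nd2 fell (-0.52 ± 0.14), and the glycolysis list had 4 lower, with Hk2 (-0.33 ± 0.07) and Pfkp (-0.43 ± 0.10), and 1 higher, the glucose transporter Slc2a3 (0.28 ± 0.06). The chaperone Hspa8 (-0.34 ± 0.10) was 1 of 3 lower TOP mRNAs. Of 36 immediate early genes 3 rose, with Btg2 (0.41 ± 0.07) and Klf2 (0.28 ± 0.08). Each of these list calls ended with an estimated correlation (adjusted p = 0.443 for all). In the mTORC1 and PI3K list the insulin receptor substrate Irs2 (0.94 ± 0.21) rose and Eif4ebp1 (-0.57 ± 0.14) and Sesn2 (-0.53 ± 0.14) fell. In the heat shock and unfolded protein response list Dnajb9 rose (0.41 ± 0.10) and 2 genes fell, and its median of -0.08 and mean of 0.08 differ in sign (adjusted p = 0.443 with an estimated correlation for both lists).

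The largest polysomal rises by the naming rule were Cacna1h (1.23 ± 0.33), the phosphodiesterase Pde1b (1.03 ± 0.24), the nuclear RNA Neat1 (1.03 ± 0.29), Ahnak (1.02 ± 0.29) and the microRNA host transcript Mir17hg (1.01 ± 0.31). The non-coding RNAs Rn7sk and Rpph1 held 0.621% to 1.19% of polysomal counts after the combination and 0.385% to 0.711% after vehicle. Whether a difference in the make-up of the fractions bears on these rises was not tested. Bmf (0.94 ± 0.24) and Pim1 (0.46 ± 0.12) rose and Rrn3 (-0.27 ± 0.07) fell, while Myc (0.09 ± 0.07) and the cAMP-activated exchange factor Rapgef4 (-0.60 ± 0.27) did not pass. The combination changed 1140 polysomal genes, 686 higher and 454 lower. The count was 706 with no count filter, 741 with a block on replicate number, 1716 with DESeq2 and 3310 without vehicle mouse 6 and combination mouse 3. Without the 4 libraries rich in Lars2 and Yam1 the calls of mt-Nd2 and Rpl35a ended.

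**Figure D2:**
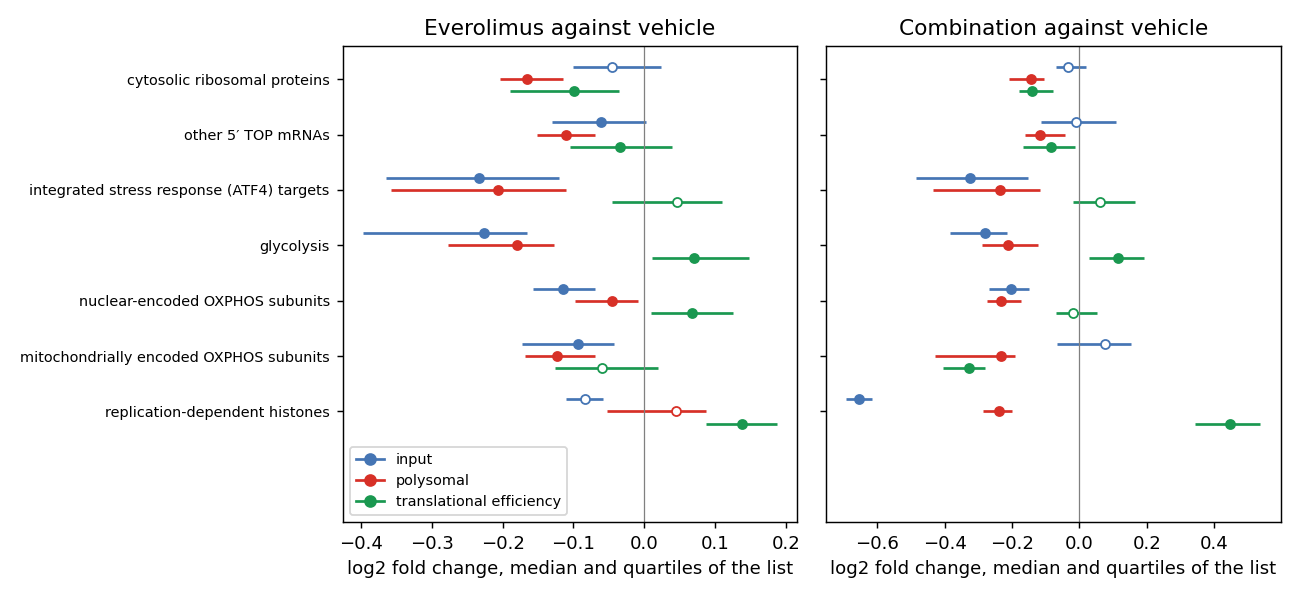
Median log2 fold change against vehicle (points) and quartiles (bars) of the genes of 7 fixed lists, after everolimus (left) and the combination (right), in the input, the polysomal RNA and translational efficiency; filled points passed camera with the preset correlation. Histones after the combination had a median of -0.66 in the input and 0.45 in translational efficiency.

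The combination was also compared with each single agent in polysomal RNA, which asks what the other drug added. Against CX5461, Ahnak (1.16 ± 0.29), Neat1 (1.13 ± 0.29) and Mir17hg (1.12 ± 0.31) were the largest rises by the naming rule. Rn7sk and Rpph1 held 0.621% to 1.19% of polysomal counts after the combination and 0.38% to 0.811% after CX5461, and the bearing of this on the rises was not tested. The chemokine Ccl7 (-0.95 ± 0.24), Pydc3 (-0.69 ± 0.18) and the transaminase Gpt2 (-0.69 ± 0.14) were the largest falls. Bmf (1.01 ± 0.24), Pim1 (0.52 ± 0.12) and the cAMP-activated exchange factor Rapgef3 (0.38 ± 0.13) were higher and Rrn3 (-0.24 ± 0.07) was lower. This comparison called 3626 genes, 2016 higher and 1610 lower. Against everolimus it called 3, all lower: Pydc3 (-1.13 ± 0.18, adjusted p = 0.0153), the chemokine Ccl8 (-1.12 ± 0.20, 0.0476) and the immunoglobulin segment Ighv4-1 (-2.03 ± 0.37, 0.0487), which lies outside the naming rule and was chosen after its values were seen. The 3 calls became 0 with the 12 libraries of the compared groups alone, 10 with no count filter and 19 without vehicle mouse 6 and combination mouse 3. Without the 4 libraries rich in Lars2 and Yam1 the calls of Ighv4-1 and, against CX5461, of Rapgef3 ended. Those 4 libraries are of vehicle and CX5461 mice, so they reach the Ighv4-1 call only through the fit shared by all groups. The interaction of the drugs, which tests whether the combination differed from the sum of the single log2 changes, called 0 genes by edgeR, with 2508 at an unadjusted p under 0.05 and 177 called by DESeq2.

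Translational efficiency, the polysomal change beyond that of the input of the same mouse, called 0 of 16421 genes by edgeR for CX5461, everolimus and the combination. The counts at an unadjusted p under 0.05 were 796, 1074 and 2147, and DESeq2 called 0, 6 and 3. With no count filter edgeR called 118, 78 and 322. After everolimus the 79 ribosomal protein genes had a median of -0.10 (8 lower adjusted over the list alone, adjusted p = 0.353 with an estimated correlation). After the combination their median was -0.14 (0 adjusted over the list alone, adjusted p = 0.431 with an estimated correlation). Histone genes had a median of 0.45 after the combination (41 higher adjusted over the list alone, adjusted p = 0.523 with an estimated correlation), and the 13 mitochondrially encoded subunits one of -0.33 (5 lower adjusted over the list alone, adjusted p = 0.329 with an estimated correlation). The TOP list had a median of -0.08 (1 lower adjusted over the list alone, adjusted p = 0.271 with an estimated correlation). After CX5461 the ribosomal protein median was -0.05 (adjusted p = 0.91 with an estimated correlation). Without vehicle mouse 6 and combination mouse 3 the combination count was 177, 170 higher and 7 lower, and it was 145 with the compared groups alone.

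**Figure D3:**
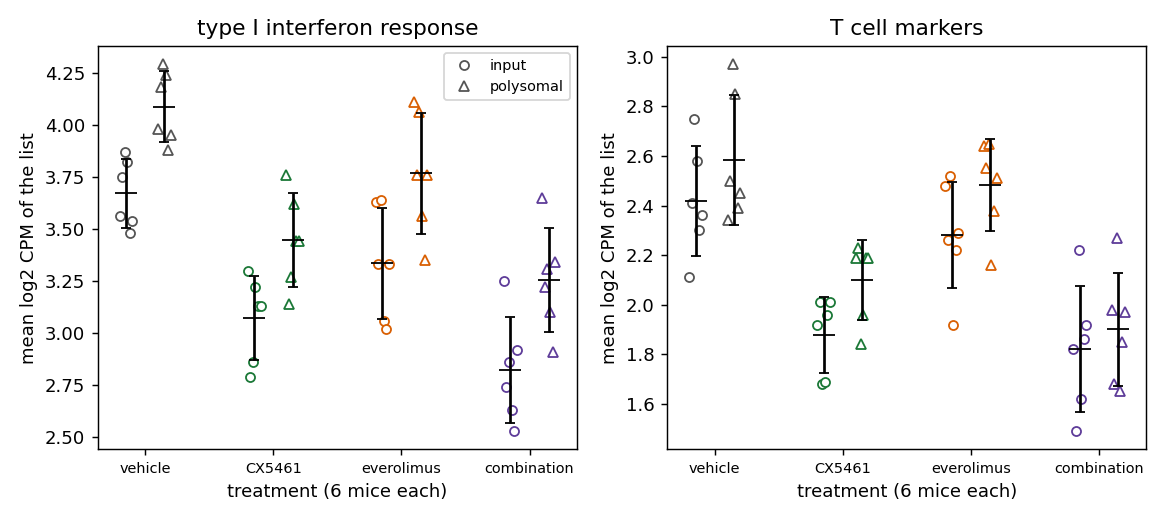
Mean log2 CPM of the type I interferon list (left) and of T cell markers (right) in each acute library, input (circles) and polysomal (triangles), with the mean and SD of each group. In the input, T cell markers were at 1.88 ± 0.15 (SD, n = 6) after CX5461 and at 1.82 ± 0.25 after the combination, against 2.42 ± 0.22 after vehicle.

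The relapse tables hold their libraries in 2 runs of input columns and 3 runs of polysomal columns, each in alphabetical order. The runs differ in pseudogene counts: Gm9341 was at 0.0447 to 0.212 CPM in the 7 inputs of the first run and at 35.8 to 56.8 in the 5 of the second. The first run of inputs holds naive lines 33 and 38, CX5461 lines 14 and 39, everolimus line 12 and combination lines 8 and 9. The polysomal libraries of CX5461 lines 14 and 39 form a run of their own, in which 760 genes were at 0 that had at least 10 counts in each of the other 10 polysomal libraries. Kmt2a, for example, had 0 polysomal counts in lines 14 and 39 with 2154 and 2291 in their inputs. No other pair of polysomal libraries had such a gene, and 0 of the 760 were at 0 in both inputs of the 2 lines. The labels do not state whether these 2 libraries were counted with another annotation. Every relapse polysomal comparison with CX5461 is therefore given also without these 2 libraries, which leaves 1 CX5461 line that is assumed to vary like the others. With the run of columns as a term, polysomal comparisons with CX5461 likewise rest on line 20, since the separate run holds no other group.

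The relapse comparisons ask how lymphomas that regrew under a drug differed from naive ones. Rn7sk and Rpph1 held 6.44% to 10.3% of input counts in naive lines and 11.3% to 14.5% in lines from drug-treated mice. This difference goes with the groups, and its bearing on the input calls was not tested. The kappa light chain V gene with the most input counts also went with the groups. It was Igkv1-117 in the naive lines and everolimus line 4, and another gene in every CX5461 and combination line. If this reflects different subclones, they cannot be told apart from treatment where CX5461 or combination lines are compared with naive lines. In the input of CX5461 lines, the Notch target Hey1 (chromosome 3, 8663359 to 8667256) was 39.8-fold higher (95% counting interval 22.6 to 77.5; 5.54 ± 0.86, adjusted p = 0.00393). The transcription factor Insm1 (5.01 ± 0.73) and the glycosyltransferase Mgat4c (30.4-fold, interval 20.9 to 46) followed. Igkv1-117, a kappa light chain segment, was 5120-fold lower (interval 1420 to 42300). Rnf43, a ubiquitin ligase that limits Wnt receptors (chromosome 11, 87662722 to 87735539), was 550-fold lower (interval 290 to 1200), and the fatty acid receptor Cd36 69.4-fold lower (interval 41.9 to 125). Myc rose by 1.00 ± 0.16 (adjusted p = 0.00446) and Polr1b by 0.67 ± 0.12. Of 74 ribosome biogenesis factors 7 rose, with Bop1 (0.74 ± 0.14) and Noc4l (0.66 ± 0.15), and 2 fell, the polymerase I subunit Polr1a (-0.74 ± 0.15) and the helicase Ddx47 (-0.57 ± 0.13). Adjusted over the list alone these were 10 and 3. Snhg12 (0.63 ± 0.12) was the 1 of 11 snoRNA host genes with a TOP tract that rose (1 adjusted over the list alone), and both list calls ended (adjusted p = 0.993 with an estimated correlation).

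CX5461 lines differed from naive lines in 1211 of 14474 input genes, 667 higher and 544 lower. The count was 365 without CX5461 line 14, 498 without CX5461 line 39, 480 without naive line 33, 640 without naive line 38, 582 with the compared groups alone and 2345 with the run of columns as a term. Of the named genes, Cd36, Hey1, Igkv1-117, Insm1, Myc and Polr1b kept their call with each line left out in turn. The calls of Bop1, Polr1a, Rnf43, Snhg12, Noc4l and Ddx47 ended without CX5461 line 14 and that of Mgat4c without naive line 33 (adjusted p up to 0.103). The Rnf43 fold was 444 without CX5461 line 14. Without CX5461 line 20 the Hey1 fold was 15.4 (interval 8.56 to 30.5). The Igkv1-117 fold, which rests on 2 counts in the CX5461 lines, was 7710 without line 20 and 3180 without line 39.

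In the input of everolimus lines, the kappa segment Igkv5-43 (4.77 ± 0.80), the integrin Itga5 (4.02 ± 0.75) and Mgat4c (10.7-fold, interval 7.24 to 16.4) were the largest rises by the naming rule. Cd36 (-3.50 ± 0.57), the Wnt receptor Fzd7 (11.6-fold lower, interval 7.82 to 17.9) and the Rac activator Tiam1 (-2.33 ± 0.67) were the largest falls. Myc (0.65 ± 0.16), Trp53, which encodes p53 (0.70 ± 0.15), and Polr1b (0.51 ± 0.12) rose. Of 30 genes of the G2/M phases 6 fell, with the mitotic genes Cenpf (-1.09 ± 0.21) and Bub1 (-0.97 ± 0.21), and 8 of 27 of the heat shock and unfolded protein response, with the chaperones Hsp90aa1 (-0.83 ± 0.17) and Canx (-0.73 ± 0.16). These were 10 and 1 higher with 11 lower when adjusted over the list alone. Rises were called for 5 of 34 immediate early genes, with Nr4a1 (0.84 ± 0.12) and Zfp36 (0.86 ± 0.15), and for 5 of 11 snoRNA hosts, with Snhg12 (0.68 ± 0.12) and Snhg7 (0.79 ± 0.15). They were called for 4 of 66 histones, with Hist2h2ab (0.82 ± 0.14) and Hist1h4d (0.81 ± 0.18), and for 2 of 22 glycolysis genes, Eno1 (0.69 ± 0.19) and Pkm (0.56 ± 0.17). Adjusted over the list alone these 4 counts were 5, 5, 2 and 3. All 6 list calls ended (adjusted p = 0.846 with an estimated correlation).

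Everolimus lines differed in 1694 input genes, 904 higher and 790 lower. The count was 90 without everolimus line 12, 201 without line 26, 991 without line 4, and 469, 880 and 916 without naive lines 6, 33 and 38. It was 680 with the compared groups alone and 4399 with the run of columns as a term. Line 12 is the only everolimus input in the first run of columns, where naive lines 33 and 38 also lie. Leaving it out therefore compares everolimus inputs of the second run alone with naive inputs of both runs. Of the named genes, Cd36, Igkv5-43 and Nr4a1 kept their call with each line left out in turn, and every other call ended without everolimus line 12 (adjusted p up to 0.139). The Fzd7 fold was 21.2 without that line. Some calls ended without other lines too: Pkm kept its call in 1 of 12 omissions and Eno1 and Tiam1 in 3, against 11 for Itga5.

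In the input of combination lines, Hey1 was 48.9-fold higher (interval 27.8 to 95.1), Spry1, an inhibitor of receptor tyrosine kinase signalling, 24.7-fold (interval 16.7 to 38) and Igkv5-43 rose by 4.57 ± 0.79. Rnf43 was 1010-fold lower (interval 433 to 3120), Igkv1-117 805-fold (interval 471 to 1510) and Cd36 76-fold (interval 45 to 139). Myc (0.88 ± 0.16), Bmf (1.03 ± 0.26), Pim2 (0.57 ± 0.17), Rapgef3 (1.25 ± 0.38) and Polr1b (0.43 ± 0.12) rose, and Cdkn1a, the p21 cell cycle inhibitor (chromosome 17, 29090976 to 29100727; -1.76 ± 0.47), and Pim1 (-0.47 ± 0.11) fell. Of 30 G2/M genes 6 fell, with the proliferation marker Mki67 (-1.13 ± 0.20) and Cenpf (-1.11 ± 0.21), and 10 of 27 genes of the heat shock and unfolded protein response, with Edem1 (-1.0 ± 0.10) and Pdia4 (-1.09 ± 0.14), of protein quality control in the endoplasmic reticulum. Of 11 snoRNA hosts 4 rose, with Snhg12 (0.70 ± 0.12) and Snhg7 (0.72 ± 0.15), and of 66 histones 2, with Hist2h2bb (1.05 ± 0.25). Adjusted over the list alone the counts were 11 lower, 13 lower with 2 higher, 4 higher and 0. The 13 mitochondrially encoded subunits had a median of -0.39 with 0 called by edgeR, and all 5 list calls ended (adjusted p = 0.979 with an estimated correlation).

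Combination lines differed in 1956 input genes, 1042 higher and 914 lower. The count was 766 without combination line 9, 946 without combination line 8, 1177 without naive line 33, 1207 without naive line 6, 1224 with the compared groups alone and 3666 with the run of columns as a term. Of the named genes, Cd36, Cenpf, Edem1, Hey1, Igkv1-117, Igkv5-43, Mki67, Myc, Pdia4, Rnf43, Snhg12 and Spry1 kept their call with each line left out in turn. Those of Bmf, Cdkn1a, Hist2h2bb, Pim2, Polr1b, Rapgef3 and Snhg7 ended without combination line 8 and that of Pim1 without combination line 9. Some ended without other lines too: Pim2 and Rapgef3 kept their calls in 2 and 3 of 12 omissions, against 11 for Snhg7. The highest adjusted p of these genes was 0.184, for Rapgef3 without combination line 9.

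**Figure D4:**
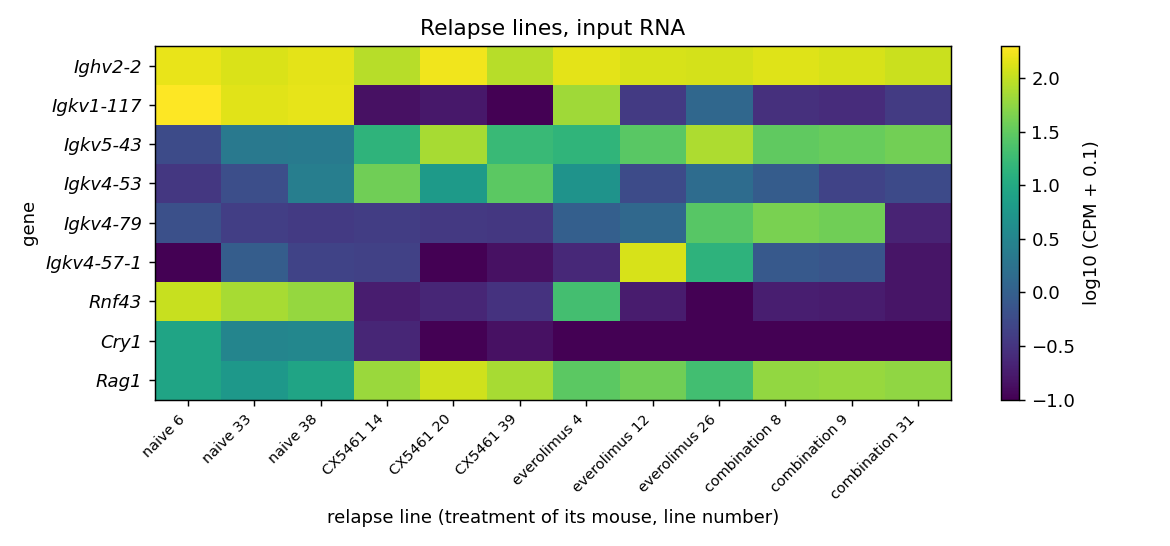
Input levels, as log10 of CPM plus 0.1, of immunoglobulin segments, Rnf43, Cry1 and Rag1 in each of the 12 relapse lines. Igkv1-117 and Rnf43 are near 0 in the 6 CX5461 and combination lines, and in everolimus line 4 they lie between these and the naive lines.

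In polysomal RNA of CX5461 lines, the protocadherin Pcdhgc4 was 316-fold higher than in naive lines (interval 208 to 504). Its polysomal counts were 4280 and 5166 in lines 14 and 39 but 9 in line 20, and the input of the 3 CX5461 lines held 11 counts, as did that of the naive lines (1.09-fold lower, interval 0.427 to 2.76), so this rise rests on the 2 libraries of the separate run. Tmem132e was 120-fold higher (interval 65.1 to 251), Lingo3 86.8-fold (interval 45.6 to 190), Enpp3 75.4-fold (interval 38.1 to 175) and Hey1 52.7-fold (interval 28.5 to 110). Unlike Pcdhgc4, Tmem132e was also high in the input of lines 14 and 39, with 314 and 593 counts, against 8 in line 20 and 0, 0 and 12 in naive lines. Igkv1-117 was 2570-fold lower (interval 1430 to 5150), Rnf43 2130-fold (interval 729 to 10300), Igkv1-110 242-fold (interval 127 to 531), the exchange factor Dock10 185-fold (interval 84.8 to 507) and Igkv3-7 167-fold (interval 101 to 299). Polr1b (0.51 ± 0.13) and Bmf (0.74 ± 0.20) rose. Of 79 ribosomal protein genes 23 rose, with Rpl24 (2.92 ± 0.59) and Rps14 (1.93 ± 0.39), and 2 fell, Rpl32 (-0.58 ± 0.12) and Rps6 (-0.69 ± 0.22). Adjusted over the list alone 28 were higher and 2 lower (adjusted p = 0.551 with an estimated correlation). Of 33 immediate early genes 7 rose, with Dusp4 (4.74 ± 0.84) and Egr2 (4.55 ± 0.98), and 1 fell (7 and 1 adjusted over the list alone). Of 66 histones 10 rose, with Hist1h2bg (1.43 ± 0.37; 0 adjusted over the list alone), and the 13 mitochondrially encoded subunits had a median of -0.90 with 0 called by edgeR; these 3 list calls ended (adjusted p = 0.984 with an estimated correlation).

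CX5461 lines differed in 2882 of 14797 polysomal genes, 1686 higher and 1196 lower, and in 527 without the libraries of lines 14 and 39, 441 with the compared groups alone and 798 with the run of columns as a term. The count was 615 and 651 without CX5461 lines 14 and 39, and 505, 580 and 1537 without naive lines 38, 33 and 6. It was 8970 without CX5461 line 20, where the CX5461 group consists of the 2 libraries of the separate run alone. Of the named genes, Dusp4, Hey1, Igkv1-110, Igkv1-117, Lingo3 and Rnf43 kept their call with each line left out in turn. The call of Dock10 ended without CX5461 line 14 and the others without naive line 33, with the highest adjusted p, 0.329, for Igkv3-7 without naive line 6. Some ended without other lines too: Igkv3-7 and Rps6 kept their calls in 2 of 12 omissions, against 10 for Rpl24 and Rps14. Without both CX5461 lines 14 and 39, Hey1, Lingo3, Enpp3, Dusp4 and Egr2 kept theirs and Pcdhgc4 was not tested, while those of Rpl24, Rps14, Rpl32, Rps6, Hist1h2bg, Polr1b, Bmf, Dock10, Tmem132e, Rnf43 and the 3 kappa segments ended. The log2 changes in CX5461 line 20 alone were then 0.49 for Rpl24, 0.44 for Rps14 and 1.79 for Tmem132e, but still -10.60 for Rnf43, -10.90 for Igkv1-117, -6.89 for Igkv1-110 and -6.22 for Dock10. Of the ribosomal protein genes 2 were then higher and 0 lower (0 adjusted over the list alone), of the histones 0 were called and of 34 immediate early genes 3 rose and 1 fell (6 and 1 adjusted over the list alone). The calls of these 3 lists with the preset correlation passed again and ended with an estimated one (adjusted p = 0.559 for ribosomal proteins and 0.789 for the others). The median of the mitochondrially encoded subunits went from -0.90 to 0.15 and its list call ended. The Igkv3-7 fold rests on naive line 6, with 1810 polysomal counts against 27 and 3 in naive lines 33 and 38, and was 4.42 without it (interval 2.3 to 8.84) and at least 510 without CX5461 line 39. The Rnf43 fold, which rests on 3 counts in the CX5461 lines, was 4340 without line 14 and 1300 without line 39. Egr2, 21.5-fold higher with all lines, was 59.5-fold higher without naive line 6. Folds without CX5461 line 20 were 22 for Hey1, 44.3 for Enpp3, 10.3 for Egr2, 387 for Igkv1-110 and 395 for Dock10. The Tmem132e fold was 65.8 without CX5461 line 39 and 285 without naive line 38, and the Lingo3 fold was 262 without naive line 33. Counts of ribosomal protein, histone and kappa genes can hold reads of related sequences, which the deposited counts do not separate.

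In polysomal RNA of everolimus lines, the homeobox gene Hoxb9 (3.82 ± 0.34, adjusted p = 0.00496), the adaptor Sh2b2 (12.1-fold, interval 8.36 to 18.2), Ipcef1 (3.06 ± 0.43), the receptor kinase Erbb3 (2.72 ± 0.35) and Igkv5-45 (17.4-fold, interval 12 to 26.2) were the largest rises by the naming rule. Tnfrsf13c, the BAFF receptor of B cells, fell by 1.37 ± 0.20. The other 2 genes called lower, the clock gene Cry1 (0 counts in all 3 everolimus lines, at least 135-fold lower) and Zfp518b (214-fold lower, interval 38 to 8500), were named after their values were seen. Everolimus lines differed in 17 genes, 14 higher and 3 lower. The heat shock and unfolded protein response, immediate early, G2/M and TCA cycle lists had medians of -0.20, 0.43, -0.16 and -0.14 with 0 genes called by edgeR, and these calls ended (adjusted p = 0.194 for the heat shock and unfolded protein response and 0.592 for the other 3 with an estimated correlation).

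The 17 calls became 0 without naive line 6, 33 or 38, 1 without combination line 9 or everolimus line 12, 5 without everolimus line 26, 10 without CX5461 line 14 or 39, 42 without everolimus line 4 and 180 without CX5461 line 20. They became 75 without the libraries of CX5461 lines 14 and 39, 118 with the compared groups alone and 538 with the run of columns as a term. The calls of all the genes named here therefore ended without naive line 38, with the highest adjusted p, 0.331, for Igkv5-45. The Igkv5-45 fold was 10.1 without everolimus line 26 and 28.2 without naive line 6. Without everolimus line 12 Cry1 was at least 75.7-fold lower and Zfp518b, then with 0 counts, at least 39.9-fold.

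In polysomal RNA of combination lines, Enpp3 was 115-fold higher (interval 58.2 to 268), Hey1 59.4-fold (interval 32.1 to 125), Spry1 42.6-fold (interval 23.6 to 86), Sh2b2 40.9-fold (interval 28.5 to 60.9), and Igkv5-43 rose by 5.35 ± 0.97. Igkv1-117 was 3520-fold lower (interval 1620 to 9580), Igkv3-7 1870-fold (interval 335 to 73900), Rnf43 796-fold (interval 365 to 2170), Dock10 138-fold (interval 63.3 to 378) and Igkv1-110 74-fold (interval 48.7 to 118). Myc (0.83 ± 0.23), Bmf (0.77 ± 0.20) and Pim2 (0.60 ± 0.16) rose, Cdkn1a (-2.08 ± 0.45) and Pim1 (-0.43 ± 0.11) fell, and Mdm2, the p53 antagonist (-0.40 ± 0.13), did not pass. Of 74 ribosome biogenesis factors 8 rose, with Tbl3 (1.12 ± 0.22) and Wdr3 (0.62 ± 0.12), and 3 fell, with Ddx47 (-0.76 ± 0.14) and Emg1 (-0.57 ± 0.11). Adjusted over the list alone these were 10 and 3. Of 30 G2/M genes 3 fell, with cyclin B2, Ccnb2 (-0.59 ± 0.10), and Kif23 (-0.57 ± 0.16), and 8 adjusted over the list alone. In the heat shock and unfolded protein response Edem1 (-1.29 ± 0.15) and Pdia4 (-1.15 ± 0.20) were among 6 of 27 that fell, against 1 that rose (7 and 1 adjusted over the list alone). Histones had a median of 0.53 with 0 called by edgeR, and all 4 list calls ended (adjusted p = 0.882 with an estimated correlation).

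Combination lines differed in 1480 polysomal genes, 707 higher and 773 lower. The count was 460, 502 and 856 without naive lines 38, 33 and 6, 639, 685 and 981 without combination lines 9, 31 and 8, and 3738 without CX5461 line 20. It was 949 with no count filter, 3141 with the compared groups alone, 3274 without the libraries of CX5461 lines 14 and 39 and 3933 with the run of columns as a term. Of the named genes, Ccnb2, Ddx47, Edem1, Hey1, Igkv5-43, Pdia4, Sh2b2 and Spry1 kept their call with each line left out in turn. Those of Igkv1-117, Igkv1-110, Igkv3-7, Rnf43, Dock10, Emg1, Kif23, Bmf, Pim1, Pim2 and Myc ended without combination line 9, that of Cdkn1a without combination line 31 and those of Enpp3, Tbl3 and Wdr3 without naive line 33. Some ended without other lines too: Kif23 kept its call in 1 of 12 omissions and Igkv3-7 and Myc in 3, against 11 for Emg1. The highest adjusted p was 0.184, for Igkv3-7 without naive line 6, where its fold was 49.5 (interval 8.23 to 2020), since that line held 1810 of the 1840 naive counts. Without combination line 9 the folds of Rnf43, Igkv1-110 and Dock10, whose calls ended there, were 775, 81.3 and 180, and Igkv3-7 was at least 405-fold lower. Its fold was 1160 without combination line 31. The folds of Enpp3, Spry1 and Igkv1-117 without combination line 9 were 71.4, 25.9 and 2280, and without naive line 6 that of Spry1 was 72.3.

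Against CX5461 lines, combination lines differed in 1 polysomal gene, Snn, which encodes stannin (1.57 ± 0.17, adjusted p = 0.024). This call ended without combination line 9 and without any naive or everolimus line or CX5461 line 14 or 39 (adjusted p up to 0.202). The count was 6752 without CX5461 line 20, which leaves that group with the libraries of the separate run alone. The count was 24 without combination line 8, 4 without combination line 31 and 0 without any other single line. It was 2 without the libraries of CX5461 lines 14 and 39, 20 with no count filter, 0 with the compared groups alone and 29 with the run of columns as a term. By edgeR 2862 genes had an unadjusted p under 0.05 and DESeq2 called 984. Against everolimus lines, Dclk2 (2.79 ± 0.54), the transcription factor Sox12 (2.70 ± 0.41) and the integrin Itgb4 (2.39 ± 0.45) were higher, and the cAMP phosphodiesterase Pde8a (-3.43 ± 0.43), Prg3 (-3.15 ± 0.48) and the peptidase Dpp4 (-2.56 ± 0.42) lower. This comparison called 104 genes, 41 higher and 63 lower. The count was 0 without everolimus line 26, where the calls of all 6 of these genes ended (adjusted p up to 0.179), 22 and 61 without everolimus lines 4 and 12, 6, 2 and 7 without combination lines 8, 9 and 31, 40, 1 and 1 without naive lines 6, 33 and 38, 44 and 41 without CX5461 lines 14 and 39 and 1440 without CX5461 line 20. It was 362 with the compared groups alone, 993 without the libraries of CX5461 lines 14 and 39 and 1679 with the run of columns as a term.

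The interaction of the drugs in relapse polysomal RNA called 0 genes by edgeR, with 1840 at an unadjusted p under 0.05 and 232 called by DESeq2. The count was 4 without everolimus line 4, 5202 without CX5461 line 20, 5 with no count filter and 70 with the run of columns as a term. Without the libraries of CX5461 lines 14 and 39 it was 0 by edgeR, with 1640 at an unadjusted p under 0.05. Translational efficiency called 0 of 15637 genes by edgeR in CX5461, everolimus and combination lines, with 3253, 1646 and 578 at an unadjusted p under 0.05 and 1642, 108 and 0 called by DESeq2. Without CX5461 line 20 the CX5461 polysomal libraries are those of the separate run alone, here and for the interaction. For CX5461 lines the count was 4730 without CX5461 line 20 and 1252 with no count filter, and with the run of columns as a term it was 2808 for everolimus and 145 for combination lines. Without the polysomal libraries of CX5461 lines 14 and 39 it was 0 by edgeR for all 3, with 888, 2326 and 925 at an unadjusted p under 0.05. In CX5461 lines the 79 ribosomal protein genes had a median of 0.32 and the 13 mitochondrially encoded subunits one of -1.27 (0 and 3 lower adjusted over the list alone, adjusted p = 0.616 for both with an estimated correlation). Without the polysomal libraries of lines 14 and 39 these medians were 0.26 and 0.13, so the fall of the mitochondrially encoded subunits rests on those libraries. In everolimus lines glycolysis genes had a median of -0.29 (0 adjusted over the list alone, adjusted p = 0.727 with an estimated correlation). In combination lines ribosome biogenesis factors had a median of 0.12 (0 adjusted over the list alone, adjusted p = 0.853 with an estimated correlation).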

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

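Of the tests reported here, the test of an exchange of labels and the test with a T cell term were written before their result was seen, and the tests on Lars2 and Yam1, on other cell types and on the naive lines were chosen only after the result was seen. Single libraries set apart from the other 5 of their group by Dixon's test at 95% numbered 8 of 184 groups tested, and chance sets apart about 1 in 20. Vehicle mouse 4 had a Myc level of 9.45 log2 CPM in the input, against 9.69 to 9.8 in the others. CX5461 mouse 4 had 25900 genes detected in the input, against 21800 to 23200, and a Pim2 level of 4.44 log2 CPM, against 4.1 to 4.21. Everolimus mouse 1 had an input total of 24.7 M counts, against 17.7 to 20.2 M. Combination mouse 6 had a Polr1b level of 7.24 log2 CPM in the input, against 7.55 to 7.61, and combination mouse 1 a Pim1 level of 6.17, against 5.81 to 5.94. Vehicle mouse 6 had a Cdkn1a level of 3.53 log2 CPM in the polysomal RNA, against 3.93 to 4.05. In everolimus mouse 1 the 100 most abundant genes held 23.2% of the polysomal counts (95% Wilson interval 23.1 to 23.2), against 17.9% to 19.2%.

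Other splits of the same mice into groups of the same size were counted, with 100 drawn for each acute comparison of 6 with 6. In the input as many genes were called in 2 splits for CX5461 (64 real, 357 in the highest other), 4 for everolimus (17, 925) and 2 for the combination (1201, 3549), the real split included. These shares lie under 0.05 but were not adjusted over the comparisons. In the polysomal RNA the share was under 0.05 for CX5461 (2 splits, 135 real and 1500 in the highest other), the combination (2 splits, 1140 and 3291) and the combination against CX5461 (1 split, 3626 and 2321). It was not for everolimus (5 splits, 23 and 353) or the combination against everolimus (6 splits, 3 and 489). Nor was it for the acute list calls (8 of 40, 101 and 125). The interaction had 0 real calls, so all 40 of 40 splits had as many whatever their result (highest other 6), and this count says nothing about chance. In several comparisons another split called several times the real count. A share under 0.05 therefore does not exclude chance or a structure of the samples other than treatment. What such splits share was looked at for the 2 mice below alone.

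In acute translational efficiency 10 of 10 splits gave as many as the real 0 (highest other 0), which a real count of 0 fixes, and 10 splits are too few for a share under 0.05. The same limit holds for the relapse comparisons with 10 splits. Against naive lines the real split had the most calls in 1 of 10 splits in the input (1211, 1694 and 1956 for CX5461, everolimus and the combination) and in the polysomal RNA (2882, 17 and 1480), with 0 in the highest other. The combination against CX5461 lines had as many in 2 of 10 (1, highest other 632) and against everolimus lines in 1 of 10 (104, highest other 1). Translational efficiency, with 0 real calls, had as many in 10 of 10 by construction, with 765, 0 and 385 in the highest other for CX5461, everolimus and the combination. The split of 385 parts the 2 runs of polysomal columns, with naive lines 33 and 38 and combination line 8 on one side, and that of 765 keeps CX5461 lines 14 and 39, which form a run of their own, together. For the relapse list calls (40 of 60; 38, 73) chance was not excluded. The interaction again had 0 real calls, so its 40 of 40 (highest other 906) says nothing about chance.

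Exchanging vehicle mouse 6 and combination mouse 3 gave the highest other split in both fractions, and leaving the 2 mice out raised the input count from 1201 to 3590. An exchange of labels is argued against by the ATF4 list, whose mean lay nearer to the other group in 0 of the 4 libraries of these mice, and the interferon list gave 0 of 4 as well. Glycolysis genes lay nearer to the other group in 3 of 4 and T cell markers in 2 of 4, both of combination mouse 3, so 2 of the 4 lists do not speak against it. Lars2 and Yam1 are argued against as the source in the input, where they took 0.0591% of the counts of vehicle mouse 6 (95% Wilson interval 0.0581 to 0.0602). In the polysomal RNA they took 10.1% of its counts, and there this stays open. In the input, reads with no gene made up 14.9% in vehicle mouse 6, against 6.07% to 10.8% in the other vehicle mice. They made up 11.5% in combination mouse 3, against 11.8% to 19.7% in the other combination mice. With the 2 mice exchanged, the groups would not overlap in this input share. In the polysomal RNA vehicle mouse 6 was at 18.6%, within the 5.79% to 26% of the others. This share was not tested as a source. What sets the 2 mice apart stays open, and no biological explanation was tested.

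Interferon-stimulated transcripts fell after CX5461 and after the combination, and T cell markers fell in the same libraries. NK cell markers fell too, by -0.48 after CX5461 and -0.65 after the combination (adjusted p = 0.0341 and 0.0151, exact permutation test, n = 6), so the fall is not confined to the T cell list, and no term for NK cells was tested. The NK cell list had low input means, at 0.12 log2 CPM after vehicle, -0.36 after CX5461 and -0.53 after the combination. The counts do not show which cells held these transcripts. Myeloid and stromal and endothelial markers did not fall as the T cell markers did, and the lowest of their medians was -0.095. This argues against a like fall in the share of those cells. The test was chosen after the result was seen and covers those lists alone, so a lower share of other cell types was not excluded. Fewer T cells in the treated nodes may account for part of the fall: with the T cell marker level as a term, the interferon median after the combination went from -0.822 (quartiles of the 26 genes -1.14 and -0.601) to -0.478 (quartiles -0.686 and -0.271). After CX5461 it went from -0.625 (quartiles -0.773 and -0.45) to -0.325 (quartiles -0.453 and -0.107). Genes called lower went from 25 and 10 to 0 and 0, and adjusted over the list alone from 25 and 24 to 11 and 0. The median SE of these genes rose from 0.177 to 0.234 and from 0.176 to 0.22, so smaller changes and larger errors both entered into the loss of calls, and their parts were not separated. Both medians lay below -0.3, the bound set beforehand for excluding T cells as the whole source, but by less than the spread of the genes. This explanation and an effect of the drugs on interferon signalling cannot be told apart.

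Transcripts of 6 genes were at 2 CPM or more in each of the 3 naive lines and under 0.5 CPM in all 6 CX5461 and combination lines, in both fractions: Cry1, Igkv1-110, Igkv1-117, Igkv9-124, Nphp4 and Rnf43. Igkv9-124 was not absent, with 0.423 CPM in the input of CX5461 line 14 against 2.7 to 3.8 in naive lines. In 2 of the 3 everolimus lines, 12 and 26, these transcripts were also low (medians of 0.0481% and 0.361% of the naive mean in the input), so the pattern is not particular to lines from CX5461 or combination mice. Of 84 choices of 3 of the 9 lines, 1, the real one, gave as many genes (0 in the next highest). The pattern was chosen from these same lines, so this count cannot exclude a chance choice. The run of columns is argued against, since 57.1% of genes parting the lines in the first run (8 of 14, exact 95% interval 28.9 to 82.3) also parted them in the second, where a run effect would give under 10%. A different subclone in the drug-relapsed lines could give the pattern, since 6 of 6 of these lines had another leading kappa V gene than the naive lines, but altered transcription would give the same, and this stays open. Receptor editing, which acts on light chain genes, would account for the 3 kappa genes on chromosome 6 and not for Cry1, Nphp4 and Rnf43 on chromosomes 10, 4 and 11.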

How the results depend on the processing

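The alternatives that leave out acute libraries, CX5461 lines 14 and 39, or add the run of columns were chosen after seeing the data; the others were fixed before. Of 328 alternative counts over 26 results, 183 lay within 1.5 times the reported count; for those that did not, the cause was not tested. RLE size factors and leaving out the block of translational efficiency moved no count beyond that. Of 2896 values of named genes under the alternatives, 2361 kept their sign and their side of the threshold. Calls of named genes ended in 363 cases with a relapse line left out, 50 with the compared groups alone and 26 with no count filter.

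DESeq2 called, in the acute input, 154 genes for CX5461, 123 for everolimus and 1921 for the combination; in the acute polysomal RNA 365, 94 and 1716, with 63 for the combination against everolimus and 177 for the interaction; in acute translational efficiency 6 for everolimus and 3 for the combination. In the relapse study it called 1896 and 2641 input genes for CX5461 and everolimus, 241 and 2505 polysomal genes for everolimus and the combination, 984 and 865 for the combination against CX5461 and everolimus, 232 for the interaction, and 1642 and 108 in translational efficiency for CX5461 and everolimus. With an estimated correlation 6 acute and 0 relapse list calls passed, and with fry 24 and 7.

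With no count filter the acute counts were 701 for the combination in the input, 83, 12 and 706 for CX5461, everolimus and the combination in the polysomal RNA, 10 for the combination against everolimus, and 118, 78 and 322 in translational efficiency. Relapse counts were 29 and 949 for everolimus and the combination in the polysomal RNA, 20 against CX5461, 5 for the interaction, 1252 for CX5461 in translational efficiency and 78 list calls. With the compared groups alone the acute counts were 35 and 685 for CX5461 and the combination in the input, 10 for everolimus and 0 for the combination against everolimus in the polysomal RNA and 145 for the combination in translational efficiency. Relapse counts were 582, 680 and 1224 in the input, 441, 118 and 3141 in the polysomal RNA, and 0 and 362 for the combination against CX5461 and everolimus. The block on replicate number gave 741 for the combination in the acute polysomal RNA.

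Without the inputs rich in Gm26870 and Gm10800 the acute input counts were 1 for CX5461 and 6 for everolimus. Without the polysomal libraries rich in Lars2 and Yam1 they were 1 and 4. Without everolimus mouse 3 everolimus counts were 8 in the input and 7 in the polysomal RNA. Without vehicle mouse 6 and combination mouse 3 counts were 75 and 3590 for everolimus and the combination in the input, 47, 44 and 3310 in the polysomal RNA, 19 for the combination against everolimus and 177 for the combination in translational efficiency. Without CX5461 lines 14 and 39 relapse polysomal counts were 527, 75 and 3274, with 2 and 993 for the combination against CX5461 and everolimus; this leaves 1 CX5461 line, assumed to vary like the other groups. With the run of columns as a term they were 2345, 4399 and 3666 in the input, 798, 538 and 3933 in the polysomal RNA, 29 and 1679 for the combination against CX5461 and everolimus, 70 for the interaction, 2808 and 145 in translational efficiency for everolimus and the combination, and 60 list calls.

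With each relapse line left out in turn, input counts ranged from 365 to 1151 for CX5461, 90 to 1803 for everolimus and 766 to 2170 for the combination. Polysomal counts ranged from 505 to 8970, 0 to 180 and 460 to 3738, from 0 to 6752 and 0 to 1440 for the combination against CX5461 and everolimus, and from 0 to 5202 for the interaction. Translational efficiency ranged from 0 to 4730 for CX5461 and was 0 throughout for everolimus and the combination, and list calls ranged from 35 to 54. Each of the highest polysomal counts, and the 4730, came without CX5461 line 20, which leaves that group with the polysomal libraries of lines 14 and 39.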

Other observations

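Relapse lines differed in their immunoglobulin light chain transcripts. In the input, the kappa V gene with the most counts was Igkv1-117 in the 3 naive lines and in everolimus line 4, Igkv4-53 in CX5461 lines 14 and 39, Igkv5-43 in CX5461 line 20, everolimus line 26 and combination line 31, Igkv4-57-1 in everolimus line 12 and Igkv4-79 in combination lines 8 and 9. The heavy chain segment Ighv2-2 was detected in all 12 lines (88.8 to 170 CPM). Rag1, part of the recombinase that joins these segments, was at 5.65 to 8.44 CPM in naive lines, at 63.7, 116 and 73.6 in CX5461 lines, at 29.3, 38.6 and 19.7 in everolimus lines and at 57.4, 61.8 and 56.3 in combination lines. Rag1 was higher than in naive lines by 3.56 ± 0.30 in CX5461 (adjusted p = 0.000134), 2.21 ± 0.28 in everolimus (0.00631) and 3.17 ± 0.29 in combination lines (0.00024), and Ighv2-2 passed in none of the 3 (adjusted p of at least 0.515). These genes were chosen after their values were seen. Of the 6 transcripts of the naive lines, everolimus line 4 held 5 at over 10% of the naive mean in each fraction, while Cry1 had 0 counts in both. The median over the 6 was 26.8% in the input and 32.1% in the polysomal RNA. Everolimus lines 12 and 26 held 0 of the 6 at over 10%, with medians of 0.0481% and 0.361% in the input and 0.031% and 0.438% in the polysomal RNA.

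Several fixed lists passed in none of the comparisons with control. Medians of the BCL2 family lay between -0.082 and 0.029 in the acute and between -0.106 and 0.323 in the relapse comparisons, those of cAMP and EPAC signalling between -0.07 and 0.075 and between -0.214 and 0.206, and those of p53 targets between -0.029 and 0.061 and between -0.084 and 0.166. Plasma cell markers lay between -0.131 and 0.117 and between -0.634 and 0.327, and adipocyte markers, tested in the acute study alone, between -0.496 and 0.237. In the acute input after everolimus the RNA polymerase I machinery had a median of -0.106 with 0 of 20 genes called by edgeR (adjusted p = 0.00509, and 0.503 with an estimated correlation). In the polysomal RNA after everolimus, autophagy and lysosome genes had a median of 0.076 (adjusted p = 0.00765, and 0.236 with an estimated correlation). Trp53 in the acute input after the combination was at -0.31 ± 0.10 (adjusted p = 0.0613).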
